A study of Rattus norvegicus with 5 samples.

How the data were processed

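RNA was sequenced from cultures of dissociated rat dorsal root ganglia, the clusters of sensory neuron cell bodies and glia beside the spinal cord. Per the labels, the ganglia came from Sprague Dawley rats of postnatal day 10, from a litter of 10 pups. Cells were plated at 5000 per well in multiwell plates, received phosphate-buffered saline (PBS, a vehicle) after 1 day and were kept for 8 days. The lysates of 3 wells were pooled in TRIzol for each sample, and libraries were made with a poly-A selection kit. All 5 samples carry the same labels, so they form 1 group with replicates 1 to 5. The labels do not say that the samples came from separate litters or cell preparations. All p-values below therefore measure only the spread between these libraries, which may be technical.

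Per the submitters' processing notes, the tools were Trim Galore 0.6.6, cutadapt 2.8 and Salmon 1.5.1, with the rat build mRatBN7.2. Salmon assigns reads to transcripts without a genome alignment. The order of the steps, the strand setting and the treatment of multiply mapping reads are not given in the sources used here. The deposited combined table holds gene-level TPM for 33014 gene symbols. TPM is the estimated count of reads divided by effective length and scaled to a total of 1000000 per library. The deposited quantification files hold, per the file headers, TPM and an estimated count of reads for each of 98811 transcripts per library. Estimated counts are model-based and need not be whole, so the deposited estimated counts were rounded to whole numbers before any count model was fitted. No mitochondrially encoded gene was found in the combined table, so the TPM values here are relative to the other genes.

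The combined table was the main source. Transcripts were joined to genes through a RefSeq table of the newer assembly GRCr8, which named 67330 transcripts (68.1%). Transcript sums below hold named transcripts alone, so they can fall short of the level of a gene. For 19270 genes, the summed TPM of the named transcripts came within 10% of the authors' gene TPM in every library. Their reads were called recovered and used for the count-based steps. These genes held between 67.1% and 67.4% of the estimated reads of a library. No coordinates are given, because the builds differ. In the GRCr8 table, 19 list genes overlap a gene whose TPM was over 25% of their own. Their levels are uncertain because the strand setting is not known; those named below are Cacnb1, Cacnb3, Clcn2, Egfl7, Mog, Oprm1, P2rx3, Piezo1, Tmem63b, Trpc5 and Trpm8. Members of families with near-identical sequence, such as the hemoglobin alpha genes Hba-a1 and Hba-a2, are likewise uncertain, since reads they share are divided by the model.

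Libraries held between 21596608 and 27913098 estimated reads. A transcript of 1 kb effective length at 1 TPM was backed by 13.3 to 17.4 reads. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A floor is the TPM that 3 reads over the 5 libraries would give, and intervals are exact Poisson limits at 95%.

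With 1 group there is no contrast between conditions, so the comparisons are between genes, and between gene lists, within libraries. The lists, pairs, tests, alternatives and naming rule were fixed before the data were examined. A gene was called detected at TPM of at least 1 in every library. There were 39 lists with 343 distinct genes, covering cell types, sensory neuron classes, ion channels, receptors, injury, signalling and proliferation. For 35 gene pairs, log2((TPM a + 0.1)/(TPM b + 0.1)) was taken in each library and tested against 0 with limma 3.58.1 (intercept only, empirical Bayes over the family). Ratios are on this scale, which understates the ratio for low genes. For 8 pairs of lists, the difference of the list medians of log2(TPM + 0.1) was tested in the same way. Adjusted p-values are Benjamini-Hochberg values within each family, two-sided, with a threshold of 0.05. The exact sign-flip test over 5 libraries has 32 sign patterns and cannot go below p = 0.0625, so it cannot pass the threshold; it stands only as an alternative. Spread between libraries was estimated with edgeR 4.0.16 (TMM factors, filterByExpr, intercept only) on the recovered reads. Whether the members of a list moved together was scored in each library as the mean of the members' gene-centred log2(TPM + 0.1), over members with mean TPM of at least 1. The SD of that score was ranked among 10000 random lists of the same size matched on expression in 20 bins, one-sided.

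The text names the 15 genes of highest mean TPM, the 3 highest members and up to 3 lowest undetected members of each list, the genes of each pair, and the 10 genes of highest edgeR tagwise dispersion at a mean TPM of at least 10. Other genes named below were chosen after their values were seen. Some genes that the rule selects are not reported here. Alternatives covered detection thresholds, pseudocounts, length normalization, the source of gene-level TPM, tools and the omission of each library. They were run with DESeq2 1.42.0, R 4.3.3 and Python 3.11.15 besides the tools above.

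The steps were tested on simulated data. Counts simulated with a biological coefficient of variation of 5% gave an edgeR estimate of 5.02% over 19270 genes. Of 400 simulated pairs with no difference, 3% were called. Of 100 pairs with a fold of 1.2, 96% were called, and of 100 with a fold of 1.5, 100%. The simulated pairs used only genes with a mean of at least 100 reads. Some tested pairs hold genes far below that, such as Oprd1 with a mean of 0.4 reads, and these rates do not cover them. Of 20 simulated lists given a common SD of 0.2 (log2), 100% had an unadjusted p under 0.05, against 8% of 100 lists given none. All simulated genes had the same coefficient of variation, unlike the measured genes, so the rates for lists need not hold for the data.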

Results

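The data were 5 RNA-seq libraries of cultured rat dorsal root ganglion cells, all from cultures that received PBS after 1 day and were harvested after 8 days. The series concerns a screen for pain drugs that reads neuronal firing with light, and these libraries describe which genes the cultures expressed. Estimated reads per library were 24795725, 23609017, 23637427, 27913098 and 21596608 for replicates 1 to 5. Values below are mean TPM ± SD over the 5 libraries unless stated otherwise.

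Cultures expressed a broad set of genes, led by housekeeping, ribosomal and cytoskeletal transcripts. Of the 33014 genes in the table, 13635 were detected in every library, and between 14208 and 14259 reached 1 TPM in single libraries. A further 8529 genes were at 0 in all libraries. The most abundant gene was Eef1a1, a translation elongation factor, at 9411 ± 182 TPM (SD, n = 5). Apoe, a lipid carrier made by glia and macrophages, followed at 9129 ± 1167 TPM and had the largest SD among the 15 most abundant genes. Vim, an intermediate filament of non-neuronal cells, was at 7944 ± 196 TPM. The iron storage genes Fth1 and Ftl1 stood at 5368 ± 290 and 4525 ± 229 TPM, and the other members of the top 15 were Tpt1, Rpl13a, Tmsb10, Rpl41, Lgals1, Rplp1, Rpl35, Rpl31, Tuba1a and Tmsb4x. The 10 most abundant genes held between 5.87% and 6.23% of each library's TPM.

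Markers of neurons, Schwann cells, satellite glia, fibroblasts and macrophages were present together in every library. All 14 pan-neuronal genes were detected. In the combined table they were led by the intermediate filament gene Prph at 2212 ± 47.7 TPM, the neuronal tubulin Tubb3 at 1664 ± 39.9 TPM and the ubiquitin hydrolase Uchl1 at 1487 ± 57.7 TPM. Transcript sums, which leave out unnamed transcripts and can be too low, put Prph at 445 TPM, below Tubb3 and Uchl1. All 9 myelinating Schwann cell genes were detected, with the myelin genes Pmp22 at 1185 ± 122 and Mbp at 872 ± 147 TPM. All 11 genes of immature or non-myelinating Schwann cells were detected, led by S100b (499 ± 16.05 TPM), the glial transcription factor Sox10 (322 ± 13.8 TPM) and Scn7a (310 ± 24.0 TPM). Satellite glia genes (7 of 7) were led by Apoe, Glul at 244 ± 15.7 TPM and Fabp7 at 166 ± 6.31 TPM. All 8 fibroblast genes were detected, with the collagens Col1a2, Col3a1 and Col1a1 at 597 ± 17.6, 388 ± 10.5 and 357 ± 21.3 TPM. All 13 macrophage genes were detected, with the complement genes C1qa, C1qc and C1qb at 502 ± 84.8, 477 ± 81.5 and 359 ± 57.5 TPM.

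Genes of vessel walls, blood and other tissues were detected in part, with contractile genes the highest of them. Of 8 endothelial genes 3 were detected, Cdh5 at 18.6 ± 1.05, Tek at 4.90 ± 0.597 and Egfl7 at 1.79 ± 0.416 TPM, while Cldn5, a tight junction gene, was at 0.0967 ± 0.0695 TPM. Mural and smooth muscle genes (6 of 8) were led by Tagln at 150 ± 33.2 and Acta2 at 110 ± 33.0 TPM, and Kcnj8 and Rgs5 were not detected. Of 8 lymphocyte genes only Cd8a was detected in this list, at 7.93 ± 1.09 TPM. Cd3d, Cd3e and Nkg7 had 0 reads, which allows up to 0.0988, 0.0526 and 0.0753 TPM over the 5 libraries. Of 7 erythroid and platelet genes 4 were detected, led by Pf4 at 68.9 ± 13.4 TPM, a chemokine gene also expressed by macrophages, and Ppbp had 0 reads (up to 0.291 TPM). The hemoglobin genes Hbb and Hba-a1 were at 4.91 ± 1.53 and 4.79 ± 0.768 TPM, and Alas2 was undetected. Aqp4, a water channel of astrocytes, was at 4.68 ± 0.740 TPM and was the only detected gene of 5 for central glia, with Opalin, Mog and Hapln2 lowest. For skeletal muscle 2 of 6 genes were detected (Tnnt3 and Acta1 at 3.21 ± 0.867 and 2.45 ± 0.853 TPM), and for adipocytes 1 of 4 (Cidec at 2.71 ± 0.573 TPM).

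**Figure D1:**
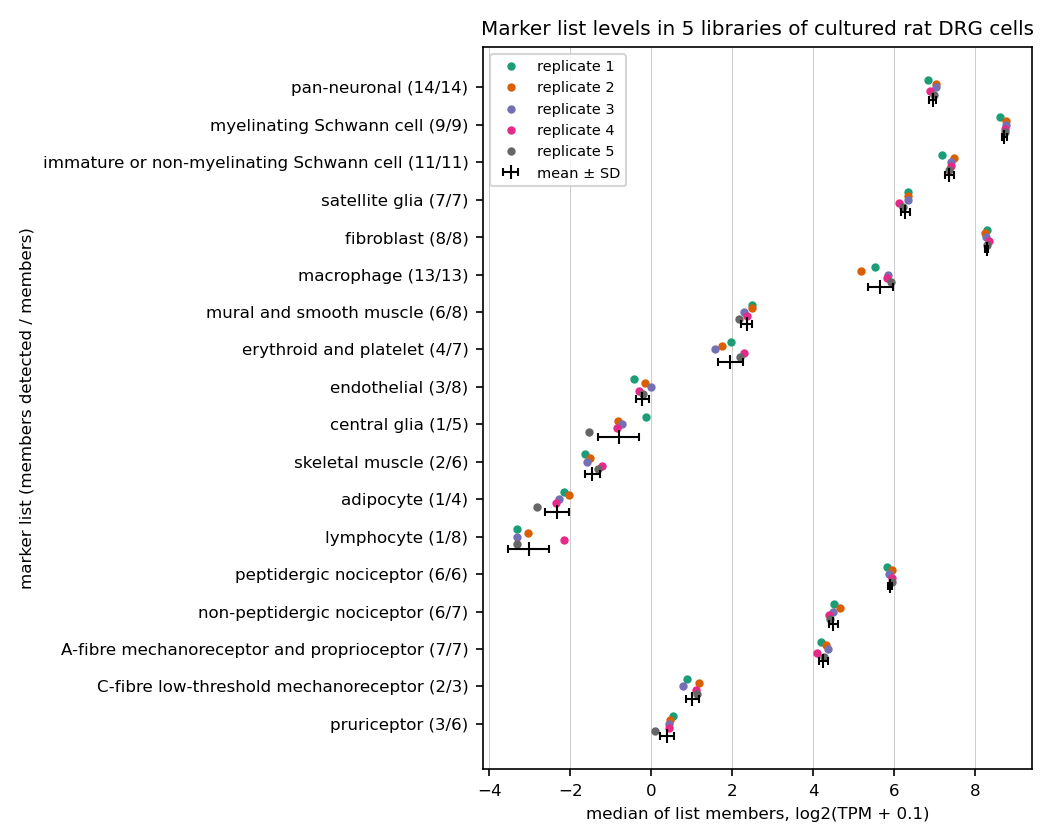
Levels of 18 marker lists in each library. The x axis is the median over list members of log2(TPM + 0.1), each dot is 1 of the 5 libraries, the bar is the mean ± SD, and the label gives members detected over members. The pan-neuronal, Schwann cell, satellite glia, fibroblast, macrophage, peptidergic and A-fibre lists had all members detected, and the macrophage list ranged from 5.19 to 5.92.

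Between lists, the pan-neuronal median lay below that of myelinating Schwann cell and fibroblast genes and above that of macrophage genes. The typical (median) member was at 123 TPM for neuronal genes, 422 TPM for myelin genes, 311 TPM for fibroblast genes and 50.5 TPM for macrophage genes. Each list median is set by its middle member or members, such as Cnp for myelin genes and Mrc1 for macrophage genes. The p-values here therefore cover the spread of those members between libraries, not the spread between members of a list. The neuronal median was lower than the myelin median by a log2 difference of -1.77 ± 0.04 (SD, n = 5; limma adjusted p = 7.43e-09) and lower than the fibroblast median by -1.33 ± 0.11 (limma adjusted p = 2.12e-07), in 5 of 5 libraries each. It exceeded the macrophage median by 1.29 ± 0.32 (limma adjusted p = 3.28e-05). Immature Schwann cell genes, at 164 TPM, lay below myelin genes by -1.36 ± 0.05 (limma adjusted p = 3.22e-08). Fibroblast genes lay 2.62 ± 0.28 above macrophage genes (limma adjusted p = 2.45e-07) and 8.50 ± 0.18 above endothelial genes (limma adjusted p = 1.32e-10). These are marker levels, not shares of cells, and several of them depend on the summary or on length normalization. With the mean of members in place of the median, the neuronal list lay 0.36 above fibroblast genes, its difference from myelin genes was -0.14 (limma adjusted p = 0.0669), and the immature minus myelinating Schwann cell difference was 0.01 (limma adjusted p = 0.849). The mean also gave 1.26 for fibroblast over macrophage genes, and detected members alone gave 5.97 for fibroblast over endothelial genes. Without length normalization, among members with recovered reads, neuronal minus myelin was -1.16, neuronal minus macrophage 2.22, immature minus myelinating Schwann cell -0.23 (limma adjusted p = 0.0482) and fibroblast minus macrophage 3.73.

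Marker genes of pain-sensing neurons (nociceptors) and of touch and position neurons were both expressed. The libraries hold RNA of all cells in the wells, so they do not show which cells expressed each gene. All 6 peptidergic nociceptor genes were detected, led by Tac1, which encodes substance P, at 99.9 ± 4.81 TPM, Calca (CGRP) at 79.3 ± 4.13 TPM and the neuropeptide gene Adcyap1 at 71.9 ± 2.53 TPM. Of 7 non-peptidergic nociceptor genes 6 were detected, with the ATP-gated channel gene P2rx3 at 264 ± 8.23 TPM, the GDNF receptor gene Gfra1 at 196 ± 9.97 TPM and Ret at 60.8 ± 3.59 TPM. The exception was Mrgprd, a receptor gene of non-peptidergic neurons, at 0.0627 ± 0.0950 TPM. All 7 genes of A-fibre mechanoreceptors and proprioceptors were detected. In the combined table they were led by Ntrk2 (31.0 ± 4.80 TPM), Necab2 (28.3 ± 2.15 TPM) and Ntrk3 (21.7 ± 1.52 TPM). Transcript sums, with unnamed transcripts left out, put Ntrk2 at 8.02 TPM, below Necab2 and Ntrk3. Pruriceptor genes, of itch neurons, were detected for 3 of 6 (Osmr at 47.9 ± 1.82, Sst at 4.67 ± 1.38, Nppb at 3.16 ± 0.893 TPM), with Hrh1, Il31ra and Htr1f undetected. C-fibre low-threshold mechanoreceptor genes were detected for 2 of 3 (Th at 3.70 ± 1.18 and Tafa4 at 2.07 ± 0.277 TPM). Among 7 vesicular transmitter genes, Slc17a6, the glutamate transporter VGLUT2, was at 66.6 ± 1.83 TPM. Slc18a2 followed at 9.56 ± 0.793 and Slc17a7 at 1.61 ± 0.238 TPM, and Chat, Slc17a8 and Slc32a1 were lowest, at 0.00804, 0.0461 and 0.0882 TPM.

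The peptidergic median exceeded the non-peptidergic median by 1.40 ± 0.12 (log2, SD, n = 5; limma adjusted p = 2.12e-07) and the A-fibre median by 1.65 ± 0.13 (limma adjusted p = 1.34e-07), in 5 of 5 libraries each. The first of these did not hold without length normalization, a setting in which transcript length also enters the difference. Among members with recovered reads, CPM (reads scaled by library size) gave -0.89 (limma adjusted p = 2.41e-07), the opposite direction, and detected members alone gave 0.69. Transcript sums gave 2.98 for the second. Each of these medians is set by middle members, Lpar3 for the non-peptidergic and Nefh for the A-fibre list. The limma p-values therefore do not cover the spread between members.

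Among voltage-gated sodium channel genes, the nociceptor channel genes Scn9a, Scn10a and Scn11a had the highest TPM after Scn7a. Of 10 alpha subunit genes 7 were detected. Scn7a, the member also on the Schwann cell list, held 83.3% ± 0.414 of the list's summed TPM. Scn9a (Nav1.7) was at 24.6 ± 1.88, Scn10a (Nav1.8) at 14.9 ± 0.526 and Scn11a (Nav1.9) at 13.2 ± 1.06 TPM. Scn9a exceeded Scn10a by 1.64-fold (log2 0.72 ± 0.08; limma adjusted p = 3.86e-06) and Scn11a by 1.86-fold (log2 0.89 ± 0.04; limma adjusted p = 4.40e-07), and Scn10a exceeded Scn11a by 1.13-fold (log2 0.17 ± 0.07; limma adjusted p = 0.00679). Scn8a, at 2.196 ± 0.139 TPM, and Scn3a, at 3.17 ± 0.127 TPM, lay below Scn9a by 10.8-fold and 7.56-fold in the combined table. Both folds depend on the source, since transcript sums put Scn8a at 0.226 TPM and Scn3a at 1.596 TPM. These sums leave out unnamed transcripts, so they can be too low. The undetected members included Scn1a at 0.661 ± 0.126 and Scn4a at 0.166 ± 0.0509 TPM. All 4 beta subunit genes were detected, with Scn3b at 45.9 ± 1.68 and Scn2b at 14.5 ± 0.521 TPM.

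Potassium channel genes were spread over many members at low levels, and Kcna6 was the highest on the 3 potassium channel lists. Of 18 voltage-gated members 14 were detected, with Kcna6 at 18.9 ± 1.06 and Kcnd1 at 9.80 ± 0.832 TPM, and Kcnd2, Kcnc1 and Kcnb2 were lowest. Kcna1 was lower than Kcna2 (3.89 ± 0.259 against 6.06 ± 1.201 TPM; log2 -0.60 ± 0.23; limma adjusted p = 0.000425). Of 12 calcium-activated, sodium-activated and inward-rectifier members 10 were detected, without Kcnj6 and Kcnn2. In the combined table this list was led by Kcnt1 (17.6 ± 1.25 TPM), Kcnj3 (12.3 ± 0.743 TPM) and Kcnn1 (10.9 ± 1.48 TPM). Transcript sums, with unnamed transcripts left out, put Kcnn1 at 6.92 TPM. Of 8 two-pore members 5 were detected, led by Kcnk10 (13.2 ± 0.529 TPM), Kcnk12 (9.60 ± 0.843 TPM) and Kcnk4 (3.45 ± 0.886 TPM). Kcnk9, Kcnk3 and Kcnk18 stayed under the threshold. All 4 HCN genes, of the pacemaker current, were detected, with Hcn3 at 10.3 ± 1.07 and Hcn2 at 7.67 ± 0.490 TPM.

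Calcium channel genes were led by Cacna1b, the N-type channel gene, and by auxiliary subunits. Of 8 alpha1 genes 6 were detected. Cacna1b, at 27.7 ± 1.93 TPM, exceeded the P/Q-type gene Cacna1a (13.0 ± 0.522 TPM) by 2.12-fold (log2 1.08 ± 0.06; limma adjusted p = 2.45e-07). Cacna1h, a T-type gene at 4.98 ± 0.588 TPM, exceeded Cacna1g (0.493 ± 0.1195 TPM) by 8.65-fold in the combined table (log2 3.11 ± 0.38; limma adjusted p = 4.73e-07), and Cacna1i was undetected. The direction turned with transcript sums (-2.54), where no transcript of Cacna1h was named and its sum was 0. All 7 auxiliary genes were detected, with Cacnb3 at 93.9 ± 2.14 TPM, Cacna2d1, the target of gabapentin, at 77.4 ± 4.00 TPM and Cacnb1 at 29.7 ± 1.75 TPM. Cacna2d1 exceeded Cacna2d2 (9.86 ± 0.545 TPM) by 7.78-fold in the combined table. This fold depends on the source, since transcript sums, with unnamed transcripts left out, put Cacna2d2 at 5.25 TPM.

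Of the TRP channel genes, 10 of 12 were detected, and Trpv2 was the highest at 34.3 ± 2.23 TPM. Trpm3 followed at 11.5 ± 0.890 and, in the combined table, Trpc1 at 8.07 ± 0.607 TPM (3.11 TPM with sums of named transcripts alone). The capsaicin receptor gene Trpv1 was at 7.66 ± 0.907 TPM, 4.44-fold below Trpv2 (log2 -2.15 ± 0.15; limma adjusted p = 5.89e-08). It exceeded the irritant receptor gene Trpa1 (5.48 ± 0.582 TPM) by 1.39-fold (log2 0.47 ± 0.29; limma adjusted p = 0.00467) and the cold receptor gene Trpm8 (3.51 ± 0.547 TPM) by 2.16-fold (log2 1.11 ± 0.22; limma adjusted p = 1.01e-05). Both calls were lost without length normalization, at 0.21 (limma adjusted p = 0.119) and -0.02 (limma adjusted p = 0.834). In that setting transcript length also enters the ratio, so it does not test the TPM difference alone. Trpc5 and Trpv4 were not detected in every library, at 0.195 ± 0.0392 and 1.19 ± 0.286 TPM.

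P2rx3 had the highest TPM of the purinergic, mechanosensitive and acid-sensing channel genes. It held 70.0% ± 0.695 of the summed TPM of 7 P2X genes, 4 of them detected, and exceeded P2rx4 (63.7 ± 3.36 TPM) by 4.15-fold and P2rx2 (1.66 ± 0.305 TPM) by 152-fold (log2 7.25 ± 0.26; limma adjusted p = 1.43e-09). P2rx7 was at 46.2 ± 3.44 TPM, and P2rx6, P2rx5 and P2rx1 were undetected. All 5 mechanosensitive channel genes were detected, with Tmem63b at 58.04 ± 2.69, Tmem120a at 48.5 ± 2.204, Piezo1 at 25.2 ± 1.90 and Piezo2, the touch channel, at 23.3 ± 1.43 TPM. Piezo2 and Piezo1 did not differ beyond the spread (log2 -0.11 ± 0.19; limma adjusted p = 0.192). With transcript sums, which leave out unnamed transcripts, Piezo2 was higher (0.32; limma adjusted p = 0.0192). Of 4 acid-sensing genes 3 were detected, and Asic1 (6.996 ± 0.360 TPM) exceeded Asic3 (3.60 ± 0.528 TPM) by 1.93-fold, with Asic2 at 1.65 ± 0.163 TPM and Asic4 undetected. Among 5 chloride handling genes 4 were detected, led in the combined table by Clcn3 at 50.7 ± 1.68 TPM. Sums of named transcripts alone gave 17.7 TPM for Clcn3. The chloride importer gene Slc12a2 (19.1 ± 1.35 TPM) exceeded the exporter gene Slc12a5 (0.373 ± 0.0825 TPM) by 41.0-fold, and Clcn2 was at 10.2 ± 0.690 TPM.

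**Figure D2:**
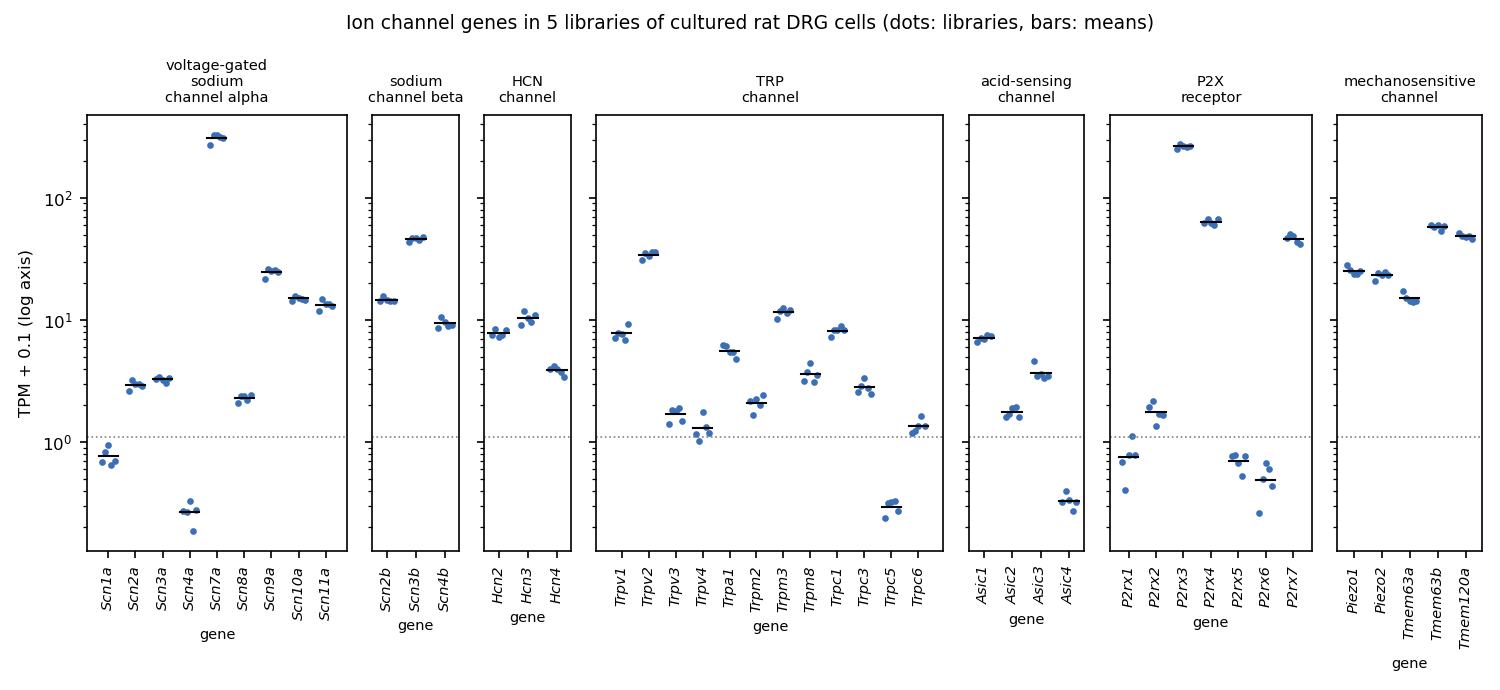
Expression of 43 ion channel genes from 7 lists, with TPM + 0.1 on a log axis. Each dot is 1 of the 5 libraries, each bar is the mean over libraries, and the dotted line marks the detection threshold of 1 TPM. Scn7a at 310 TPM and P2rx3 at 264 TPM were the highest of these genes.

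Receptors for inflammatory mediators were widely expressed, with 24 of 31 genes detected. The highest were Tnfrsf1a, a TNF receptor gene, at 150 ± 5.76, Il6st (gp130) at 104 ± 3.53 and the interferon gamma receptor gene Ifngr1 at 85.4 ± 4.07 TPM, while Hrh2, Htr1d and Ccr2 were lowest. Tnfrsf1a exceeded Tnfrsf1b (5.91 ± 0.845 TPM) by 25.1-fold and Il6st exceeded Il6r (9.81 ± 0.353 TPM) by 10.5-fold. The bradykinin receptor gene Bdkrb2 was at 19.1 ± 0.459 TPM, against 0.128 ± 0.104 TPM for Bdkrb1 (log2 6.54 ± 0.72; limma adjusted p = 2.60e-07). Among prostaglandin E2 receptor genes, Ptger4 (2.02 ± 0.134 TPM) lay below Ptger3 (11.9 ± 0.877 TPM; log2 -2.50 ± 0.14; limma adjusted p = 1.77e-08) and below Ptger2 (4.53 ± 0.676 TPM; log2 -1.12 ± 0.16; limma adjusted p = 2.37e-06). The last direction turned without length normalization, where transcript length also enters the ratio, at 0.37 (limma adjusted p = 0.000453).

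Among inhibitory Gi-coupled receptor genes, 9 of 16 were detected, led by Gabbr1 (GABA-B receptor) at 190 ± 6.40, Npy2r at 16.7 ± 1.46 and the kappa opioid receptor gene Oprk1 at 13.7 ± 0.587 TPM. The mu opioid receptor gene Oprm1, at 3.14 ± 0.531 TPM, lay 4.30-fold below Oprk1 (log2 -2.11 ± 0.24; limma adjusted p = 4.40e-07) and above the delta receptor gene Oprd1 (0.0242 ± 0.0333 TPM; log2 4.73 ± 0.43; limma adjusted p = 1.02e-07). Oprd1, Sstr1 and Oprl1 were the lowest of the list. The cannabinoid receptor gene Cnr1 (1.66 ± 0.111 TPM) exceeded Cnr2 (0.914 ± 0.0691 TPM) by 1.73-fold. Of 14 ligand-gated transmitter receptor genes 10 were detected, with Glra1, Chrnb4 and Htr3a lowest. In the combined table this list was led by Chrnb2 (25.01 ± 1.11 TPM) and Gabra2 (17.0 ± 0.596 TPM). Transcript sums put Gabra2 at 0.106 TPM, with unnamed transcripts left out, so this value can be too low.

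All 8 neurotrophic factor receptor genes were detected, with Ngfr at 286 ± 30.3, Gfra1 at 196 ± 9.97 and Gfra3 at 124 ± 6.51 TPM. Genes of axon injury and regeneration were abundant, and all 15 were detected. The growth cone gene Gap43 was at 1635 ± 7.78, the stress gene Gadd45a at 774 ± 16.8 and the transcription factor gene Jun at 377 ± 19.7 TPM. No uninjured or uncultured ganglion was measured here, so these are levels and not changes. Among 14 cytokine and trophic factor ligand genes 11 were detected, led by Ccl2 at 61.1 ± 7.78, Tgfb1 at 44.7 ± 3.08 and Lif at 15.1 ± 2.29 TPM. Il1b (0.444 ± 0.444 TPM), Ptgs2 (0.814 ± 0.290 TPM) and Tnf (1.37 ± 0.363 TPM) were under 1 TPM in at least 1 library. All 8 proliferation genes were detected at low levels, led by Cdk1 (12.4 ± 0.570 TPM), Birc5 (10.1 ± 0.825 TPM) and Top2a (6.48 ± 0.665 TPM).

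Over the whole family of 35 gene pairs, the first gene was higher in 26 and the second in 7 at a limma adjusted p under 0.05. Piezo2/Piezo1 was among the 2 pairs that did not pass. The peptide gene Calca was lower than Tac1 (log2 -0.33 ± 0.09; limma adjusted p = 0.000361). Slc17a6 exceeded Slc17a7 by 39.3-fold. Of the 20 passing pairs with recovered reads for both genes, 17 kept their call and direction without length normalization. With transcript sums, 28 of 214 named genes moved by over 1.5 times, 16 of them detected, among them Prph (445 TPM), Ntrk2 (8.02 TPM), Gabra2 (0.106 TPM), Cacna1b (6.58 TPM), Clcn3 (17.7 TPM) and Tmem63b (21.9 TPM). Transcripts that the reference table does not name are left out of these sums.

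**Figure D3:**
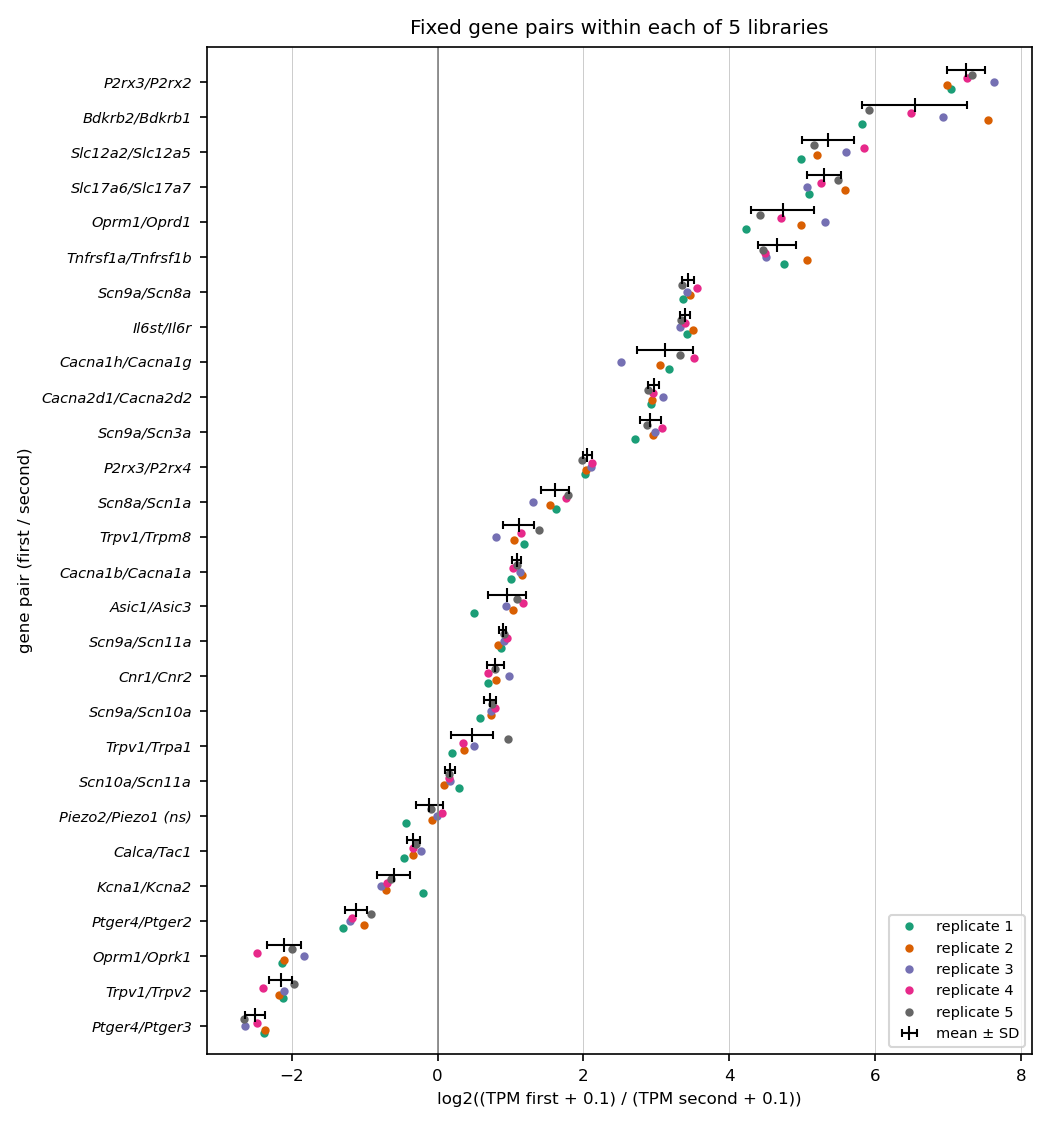
Log2 ratio of TPM + 0.1 for 28 of the 35 gene pairs, sorted by mean. Each dot is 1 of the 5 libraries, the bar is the mean ± SD, and ns marks Piezo2/Piezo1, with a limma adjusted p of 0.192. The ratios ran from -2.50 for Ptger4/Ptger3 to 7.25 for P2rx3/P2rx2.

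The Calca gene can yield either calcitonin or CGRP through alternative splicing. Its TPM was divided mainly between 2 of its 4 annotated transcripts, which held 54.1% ± 2.87 and 45.1% ± 2.97 (SD, n = 5). The other 2 held 0.640% ± 0.618 and 0.213% ± 0.226. Which product each transcript encodes was not analysed here.

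The libraries resembled each other closely, and the ribosomal RNA Rn5-8s had the highest tagwise variation among 5957 genes with recovered reads and a mean TPM of at least 10. The common biological coefficient of variation was 5.01% over 8871 genes (edgeR), and Pearson correlations of log2(CPM + 1) across genes lay between 0.998 and 0.999 for the 10 pairs of libraries (genes are not independent replicates). Chi-square per degree of freedom between pairs lay between 2.69 and 8.99, so no pair looked like 1 library deposited in duplicate. This check says nothing on whether the samples were prepared separately. The 10 highest tagwise values were those of Rn5-8s (48.6%), Apln (24.6%), LOC120093067 (20.7%), Rflna (20.6%), Ndufa4l2 (20.5%), Actg2 (20.1%), Rn18s and Rn28s (19.5% each), Acta2 (19.1%) and Bcl2a1 (18.7%). Summed TPM of Rn18s, Rn28s and Rn5-8s was 867, 1821, 1477, 1001 and 693 in replicates 1 to 5. Actg2 and Acta2, both smooth muscle actin genes, fell in order from replicate 1 to replicate 5. Actg2 went from 24.9 to 9.49 TPM and Acta2 from 149 to 62.2 TPM.

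Contractile, macrophage and myelin genes had the largest score SDs of the 30 lists. The macrophage score was lowest in replicate 2 at -0.35 (SD over libraries 0.22), the myelinating Schwann cell score in replicate 1 at -0.33 (SD 0.19), and the mural and smooth muscle score in replicate 5 at -0.34 (SD 0.22). None of 30 lists, a count of 0, passed the random-list permutation test after adjustment, with 6 at an unadjusted p under 0.05. By permutation these were pan-neuronal (p = 0.0124), myelinating Schwann cell (p = 0.0150), macrophage (p = 0.0156), immature or non-myelinating Schwann cell (p = 0.0200), mural and smooth muscle (p = 0.0317) and A-fibre (p = 0.0371), with adjusted p of 0.150 for the first 4 and 0.185 for the others. The count was 7 of 30 with the median of members, 5 of 23 with TMM-normalized log2 CPM and 1 of 30 with a pseudocount of 1. In the simulated lists without common movement, 8% had an unadjusted p under 0.05.

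**Figure D4:**
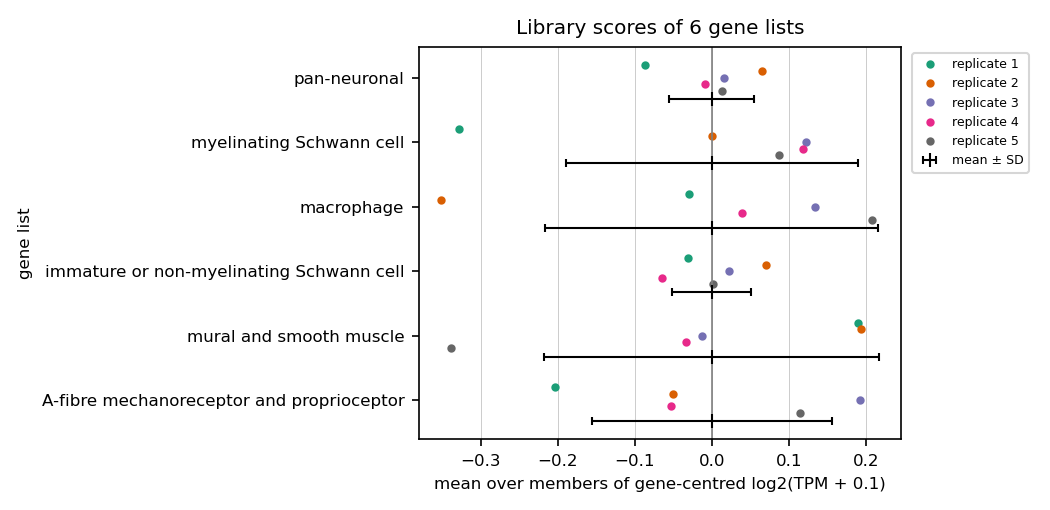
Score of the 6 lists with an unadjusted p under 0.05, as the mean over members of gene-centred log2(TPM + 0.1). Each dot is 1 of the 5 libraries and the bar is the mean ± SD. The macrophage score of replicate 2 (-0.35), the myelin score of replicate 1 (-0.33) and the mural score of replicate 5 (-0.34) lie farthest from 0.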

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

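Of 328 values tested, 16 had 1 library set apart from the other 4 by Dixon's criterion, where chance gives about 1 in 20, or 16.4. Replicate 1 accounted for 7 of them. The tests on myelin share by the immature Schwann cell score and on depth for macrophage genes were chosen only after the result was seen. The held-out gene lists were drawn up after the list scores were seen.

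Among single genes, replicate 1 was set apart by a high Asic3 (4.53 TPM, others 3.23 to 3.52) and a low Pmp22 (970 TPM, others 1214 to 1272). Replicate 2 had a low Ftl1 (4122 TPM, others 4587 to 4686), a high Scn2b (15.5 TPM, others 14.2 to 14.4) and a low Tnf (0.734 TPM, others 1.46 to 1.66). Replicate 3 had a low Rpl35 (3850 TPM, others 4059 to 4115) and, near the floor, a high Hrh2 (0.0381 TPM). Replicate 4 had Alas2 at 0.106 TPM, against 0 in the others. Replicate 5 had a high Il1b (1.22 TPM, others 0.133 to 0.373).

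Among list medians in log2(TPM + 0.1), the lymphocyte list was high in replicate 4 (-2.15, others -3.32 to -3.03), which rests on members near 0 TPM. The pruriceptor list was low in replicate 5 (0.093, others 0.43 to 0.53). The Scn9a/Scn10a ratio was low in replicate 1 (0.58, others 0.73 to 0.79), the Kcna1/Kcna2 ratio was high there (-0.20, others -0.77 to -0.64), and the score of calcium channel auxiliary genes was low there (-0.074, others 0.01 to 0.03).

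The myelinating Schwann cell list was set apart in replicate 1 in its median (8.61, others 8.73 to 8.77), which is the level of Cnp alone. Its score was also set apart there (-0.33, others up to 0.12). The A-fibre and pan-neuronal scores were also lowest there, at -0.20 and -0.086. A lower share of Schwann cell RNA as a whole would lower immature Schwann cell genes by a similar amount. Their score in replicate 1 was -0.030, so over the list they did not fall by a similar amount. Their median was lowest there (7.18, others 7.36 to 7.47), but it is the level of 1 gene, Ncam1. Members went different ways, with Gfap and Scn7a lowest in replicate 1 and Ngfr highest there. With such members and only 1 library set apart, this comparison cannot decide on that explanation. Of 10 myelin genes kept out of the fixed list, such as Mal, Pmp2 and Cldn19, 70.0% were lowest in replicate 1, against 24.0% of genes at 10 TPM or more. A smaller amount of myelin gene RNA in the pooled wells of that sample therefore stays open as a candidate explanation. With 1 group, no biological explanation was tested.

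Macrophage genes were lowest in replicate 2. Of 16 macrophage genes kept out of the fixed list, such as Lyz2, Ctss and Fcer1g, 93.8% were lowest there as well, against 15.6% of genes at 10 TPM or more. Sequencing depth does not account for it, since replicate 3, whose depth differed from that of replicate 2 by 0.1203%, had a macrophage score higher by 0.49 ± 0.05 (log2, SE over 13 members). Transcript length cannot be told apart at this precision: random lists matched on length as well gave a permutation p = 0.0489, which lies within 2 standard errors of the drawing (0.00216) of the threshold of 0.05. This test compares the size of the SD and not which library was lowest. The same matching gave a permutation p of 1e-04, the smallest it can give, for myelinating Schwann cell and for mural genes, without adjustment. These draws used only genes with recovered reads. On the CPM of those genes without length matching, the permutation p was 1e-04 for macrophage and myelin genes and 5e-04 for mural genes. The low values are therefore not particular to length matching. Different amounts of macrophage RNA in the pooled wells may explain the pattern, and no biological explanation was tested.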

How the results depend on the processing

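The transcript-level spread and the Calca range were chosen after seeing the data, as was the restriction of the planned 10-read threshold to genes with recovered reads. Genes detected kept within 1.5 times of 13635 under every threshold and source tried (11253 to 14620), and with each library left out (13682 to 13705). Among genes with recovered reads, 8904 had at least 10 reads in every library, against 8134 at 1 TPM. List genes detected numbered 266, with 246 to 279 under the alternatives; of those with recovered reads, 217 had at least 10 reads, against 200 at 1 TPM. The counts of 26 and 7 gene pairs were the same with each pseudocount and each library left out, and the 33 pairs kept their direction in those settings. Leaving out each library in turn gave 53.2% to 55.1% for the leading Calca transcript, 4.30% to 5.41% for the coefficient of variation and 0 covarying lists.

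The exact sign-flip permutation test called 0 pairs either way and none of the 8 list differences (-1.33, -1.77, 1.29, -1.36, 2.62, 8.50, 1.40 and 1.65), because its smallest p is 0.0625. With the mean of members in place of the median, neuronal minus fibroblast turned to 0.36, immature minus myelinating Schwann cell to 0.014, and neuronal minus myelinating Schwann cell was -0.14 and no longer past the threshold; the cause was not tested. Without length normalization, peptidergic minus non-peptidergic turned to -0.89. For lists, that setting leaves out members without recovered reads, and the cause was not tested. Trpv1/Trpm8 turned to -0.016 and Ptger4/Ptger2 to 0.37. Both genes of each pair had recovered reads, so for them the setting differed mainly in the dropped length division. With that division dropped, transcript length enters the ratio. With transcript sums, Cacna1h/Cacna1g turned to -2.54 because no Cacna1h transcript was named, and Piezo2/Piezo1 turned to 0.32, where Piezo1 was lower in the sum (18.7 TPM) than in the combined table. The coefficient of variation was 5.91% with DESeq2 dispersions and 22.6% over all transcripts. Covarying lists numbered 7 with the median of members, 5 with log2 CPM and 1 with a pseudocount of 1, against 0; the cause was not tested. For single genes, pairs and lists, 2063 alternatives gave the same call or a value within the spread, 41 moved a value or count, 13 gained a call and 34 lost one, 33 of them through the sign-flip test.

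Rescaling without mitochondrially encoded genes was not run, as none was found in the table. No paired analysis was possible because the labels give 1 group. Depth limits the low genes: 1 TPM over 1 kb was 13.3 to 17.4 reads per library.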

Other observations

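The lists in the next paragraph were drawn up only after seeing the data, as were the choice of the genes named there and the test on the read depth of Mrgprd. The lists carry no test.

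Of 17 neuropeptide and secretory granule genes 13 were detected, at levels that differed widely between members. The granule genes Pcsk1n, Vgf and Scg2 were at 615 ± 41.7, 301 ± 16.6 and 185 ± 11.5 TPM (SD, n = 5), and Cck at 63.3 ± 6.77 TPM, while Chga and Penk were at 8.34 ± 0.840 and 7.53 ± 1.57 TPM, and Crh and Nmu were listed at 0. All 8 transcription factor genes of sensory neurons were detected, led by Prdm12 (40.7 ± 2.96 TPM) and Tlx3 (37.2 ± 3.02 TPM). Of 7 sympathetic neuron genes only Maoa, at 47.4 ± 2.46 TPM and expressed widely, was detected, and Dbh, the noradrenaline enzyme gene, was at 0.0141 ± 0.0194 TPM. Of 10 chemokine genes 8 were detected, with Ccl6 at 274 ± 65.6 TPM, and all 12 cholesterol synthesis genes were detected, with Hmgcs1 the highest (132 ± 5.07 TPM). Of 6 T cell genes 3 were detected beside Cd8a, namely Cd4 (36.2 ± 7.40 TPM, also a rat macrophage gene), Lck (1.70 ± 0.236 TPM) and Cd8b (1.47 ± 0.154 TPM), while Cd3g was at 0.559 ± 0.379 TPM. Of 8 measurable smooth muscle genes kept out of the fixed list, 8 were lowest in replicate 5, against 19.1% of genes at 10 TPM or more. Their median gene-centred log2(TPM + 0.1) was 0.115, 0.057, -9.1e-06, -0.033 and -0.190 in replicates 1 to 5. Acta2 and Actg2 fell in the same order, and the cause was not tested.

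P2rx3 was high, at 264 TPM, while Mrgprd, a gene of the same neuron class, had 3 reads over the 5 libraries. Too few reads cannot be the cause, because the exact Poisson upper limit for Mrgprd was 0.168 TPM. Reads of Mrgprd assigned to relatives stay open: the other Mrgpr genes summed to 53.8 TPM, mostly Mrgprf (29.0 TPM) and Mrgpre (21.6 TPM), and their sequences were not compared. The reference table lists 1 gene overlapping P2rx3, Ssrp1 at 117 TPM, which could add to the P2rx3 level. The Ssrp1 level cannot tell by how much, since reads given to P2rx3 are not counted in it. A loss of Mrgprd expression in culture, or in animals of this age, is a further hypothesis that was not tested, since no uncultured ganglion was measured.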
